A study of Mus musculus with 12 samples.

How the data were processed

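Poly(A) RNA from the prefrontal cortex of 12 mice, 6 labelled tCI and 6 labelled pCI, was made into libraries with a dUTP step that marks the second strand and was sequenced from both ends, per the labels' protocols. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without their roles, and the mouse build mm10. The deposited values are whole-number counts per gene for 41096 genes and 12 libraries, with no normalization by the authors visible in them, since the totals differ between libraries. The step that made the counts, and whether it used strand, is not given in the sources used here. Counts of overlapping genes, of antisense genes and of near-identical gene copies are therefore uncertain.

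The gene identifiers in the table carry the prefix of the C57BL/6NJ strain annotation, which is not that of mm10. How the notes and the identifiers fit together is not given in the sources used here. The reference tables used here (gene names and RefSeq genes) matched 0 of the identifiers, so no gene is given a name or a position. The gene lists, the scores of cell types and brain regions, the fixed panel of genes, the share of mitochondrially encoded genes and the count restricted to genes with symbols, all planned before the data were examined, need symbols and were not run. The planned rule for named genes also needs symbols. In its place, chosen after the symbols proved missing, the 2 genes with the smallest edgeR p in each direction among those with a mean of at least 1 CPM are named.

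Low counts fell on even values, and among these on multiples of 4, more often than on their neighbours. Of 84429 entries from 1 to 40, 28.2% were multiples of 4, which ranged from 26.4% to 29.6% across the libraries, and a multiple of 4 was 1.60 times as frequent as its immediate neighbours, which are odd, and 1.19 times as frequent as the even values 2 away. The unit of 1 count is therefore not certain to be 1 fragment. An alternative that divides the counts by 4 was run for this reason. Library totals are in these units, between 40964630 and 67480907.

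Each library was assigned to its group and replicate number by its labels. All 12 columns of the table were used. No 2 libraries held identical values, and the smallest chi-square between any 2, on counts divided by 4, was 4.22 per degree of freedom, so every library was counted as a separate sample. Genes were kept by edgeR's filterByExpr, which left 18394 and removed 22702. Counts were scaled by TMM factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of pCI against tCI without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.265 and the median prior degrees of freedom 4.22. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives, and 16 genes whose DESeq2 adjusted p is NA were left as NA. CPM values are scaled by the TMM factors, and log2 CPM uses a prior count of 2. The SE printed with an edgeR log2 fold change was back-calculated. It is the size of the fold change divided by the square root of the quasi-likelihood F statistic, and edgeR does not estimate it directly.

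Single values per library were compared with an exact two-sided permutation test over all 924 assignments of 6 of the 12 libraries, whose smallest p is 0.00216. Two-group division of the whole profile was tested as the share of the summed squared deviations in log2 CPM that lies between the groups, over the same assignments. Groups of co-varying genes were made from genes with a mean of at least 1 CPM and an SD of log2 CPM over 0.6, by average linkage on 1 minus the correlation, at a height of 0.3, with at least 10 genes. The level of a group is the mean log2 CPM of its genes. This step and its settings were chosen after seeing the data, after counting how many genes passed several SD minimums, and the grouping itself did not use the labels.

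The steps were tested on simulated data, a single draw per setting, from the means, totals and edgeR per-gene dispersions of these libraries. These data covered pCI against tCI over 18394 genes. Among 200 changed genes, edgeR recovered 31.3% at 1.5-fold, 68.7% at 2-fold and 90.9% at 4-fold, with 5 false among 132 calls. DESeq2 recovered 40.3%, 77.6% and 92.4%, with 36 false among 176 calls. A further simulation set no difference except in a planted co-varying group of 60 genes, raised in more tCI than pCI libraries. There edgeR made 0 calls and DESeq2 made 7, which may include planted genes. All 60 of the 60 planted genes were found as a group. They were drawn from genes above a minimum level, raised strongly and given capped dispersions. Their recovery therefore says little about groups of low-abundance or more variable genes.

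The alternatives fixed before the data were examined were other scalings (RLE, library size alone, upper quartile), no filter or a filter of mean CPM of at least 1, DESeq2, limma-voom with and without sample quality weights, leaving out each library in turn, the replicate number as a block, the number in the titles as a covariate, 1 surrogate variable (sva 3.50.0) and other thresholds. Added after seeing the data were a robust quasi-likelihood fit, thinning of every library to the smallest total, counts divided by 4, leaving out tCI replicate 6 and pCI replicate 2 together, DESeq2 without each library, and other settings of the gene groups and the whole-profile test.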

Results

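Bulk RNA sequencing was carried out on the prefrontal cortex of mice, taken on day 35 after a traumatic brain injury. The series title places the work in the study of lasting cognitive impairment after such an injury. The labels divide the 12 libraries into 6 of a group called tCI, described as control, and 6 of a group called pCI, described as experimental. Neither abbreviation is spelled out there, so both are kept as given. The design text gives 6 animals per group, and the libraries of a group were treated as biological replicates. The files give a whole-number count for each of 41096 genes in each library. The comparison that the design implies is pCI against tCI, which asks how the prefrontal transcriptome differed between the 2 groups of mice at that time.

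The counts of a library summed to between 40964630 in tCI replicate 6 and 67480907, or 67.5 M, in pCI replicate 2. The mean total was 46.1 ± 3.83 M in tCI and 56.3 ± 8.23 M in pCI (SD, n = 6 each), a difference of 10.2 M (exact two-sided permutation test, p = 0.0195, and 0.0584 after Benjamini-Hochberg adjustment over 3 measures of library composition). The number of genes with at least 1 count was 22528.5 ± 399 in tCI and 22661 ± 430 in pCI (SD, n = 6, exact permutation p = 0.574). The 50 most abundant genes took 9.69 ± 0.199% of the counts in tCI and 9.56 ± 0.207% in pCI (SD, n = 6, exact permutation p = 0.290). Of the 41096 genes, 12055 had no count in any library and 18394 had enough counts to be tested.

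In the edgeR quasi-likelihood test 0 genes differed between pCI and tCI at an adjusted p under 0.05, with 1083 at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 41. The mean level of a set of 11 genes that varied together across the libraries was lower in all 6 pCI libraries than in any tCI library. Among genes with a mean of at least 1 CPM, the 2 with the smallest p in each direction are described: 2 low-abundance genes with lower levels in pCI, both members of that set, and 2 with higher levels in pCI. Other genes with lower levels in pCI had a smaller p than the latter pair. The genes are known here only by the identifiers of the count table, which do not pair with gene symbols in the reference tables used, so no function is given for them.

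Of the genes with lower levels in pCI, MGP_C57BL6NJ_G0011451 had the smallest p. Its level was 4.06 ± 2.12 CPM (counts scaled to a common library total) in tCI and 0.735 ± 0.208 CPM in pCI (SD, n = 6), and its log2 fold change was -2.46 ± 0.41 (SE; edgeR adjusted p = 0.170). The tCI libraries lay between 0.917 and 6.01 CPM and the pCI libraries between 0.378 and 1.03 CPM, so the groups overlapped. The second, MGP_C57BL6NJ_G0013263, was at 2.41 ± 1.51 CPM in tCI and 0.0794 ± 0.101 CPM in pCI (SD, n = 6), a log2 fold change of -4.96 ± 0.84 (SE; edgeR adjusted p = 0.170), which was -5.73 without pCI replicate 6. It had 655 counts over the tCI libraries and 24 over the pCI libraries, among which replicates 2 and 3 had 0. Every tCI library lay above every pCI library for this gene. For both genes, tCI replicates 1 and 5 were the lowest of their group, at 1.95 and 0.917 CPM for MGP_C57BL6NJ_G0011451 and at 0.389 and 0.578 CPM for MGP_C57BL6NJ_G0013263.

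Of the genes with higher levels in pCI, MGP_C57BL6NJ_G0033734 was at 0.561 ± 0.223 CPM in tCI and 9.28 ± 9.35 CPM in pCI (SD, n = 6). Its log2 fold change was 4.05 ± 0.73 (SE; edgeR adjusted p = 0.171), and 3.18 in limma-voom with sample quality weights. The pCI libraries ranged from 0.763 CPM in replicate 5 to 18.3 CPM in replicate 2 and 23.4 CPM in replicate 1, and the lowest of them lay within the tCI range of 0.255 to 0.836 CPM. MGP_C57BL6NJ_G0033950 was the more even of the pair, at 31.9 ± 3.19 CPM in tCI and 41.6 ± 1.77 CPM in pCI (SD, n = 6). Its log2 fold change was 0.38 ± 0.08 (SE; edgeR adjusted p = 0.198), and all pCI libraries, from 39.8 to 44.3 CPM, lay above all tCI libraries, from 27.9 to 36.6 CPM. Leaving out tCI replicate 5, the lowest tCI library for MGP_C57BL6NJ_G0011451, gave that gene an edgeR adjusted p of 0.0139. With any other single library left out, its edgeR adjusted p ran from 0.0508 (without tCI replicate 1) to 0.489 (without tCI replicate 3).

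**Figure D1:**
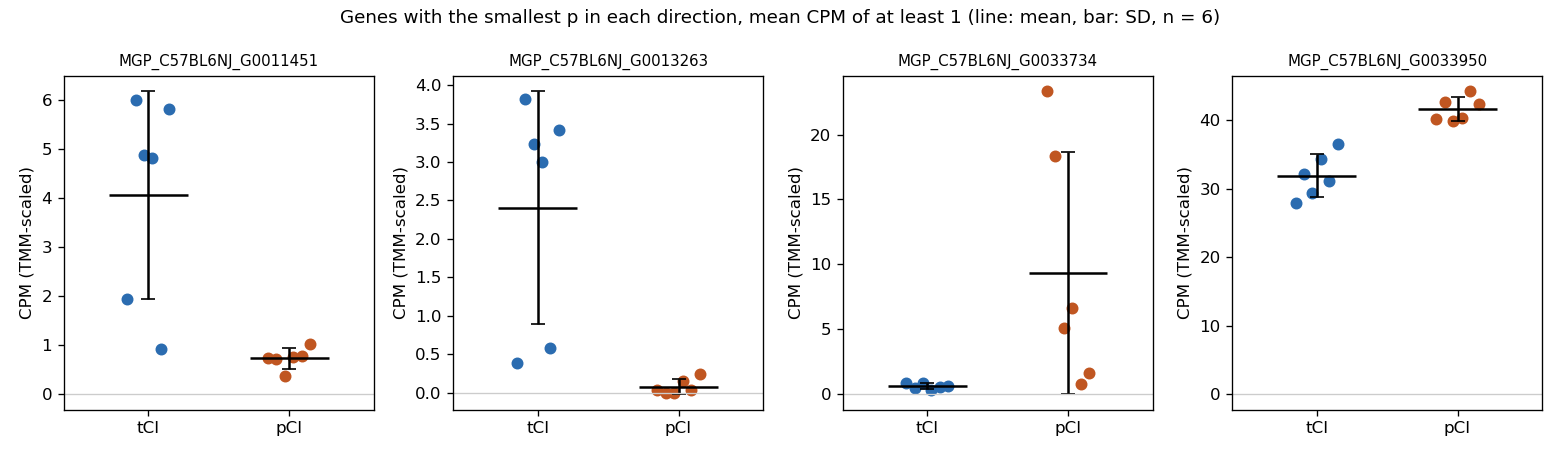
CPM of the 2 genes with the smallest p in each direction among those with a mean of at least 1 CPM, 1 point per library, with the mean (line) and SD (bar) of the 6 libraries of tCI and pCI. The pCI values of MGP_C57BL6NJ_G0033734 spread from 0.763 to 23.4 CPM, while those of MGP_C57BL6NJ_G0033950 all lie between 39.8 and 44.3 CPM.

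Across all tested genes, edgeR called 0 genes higher and 0 lower in pCI, with a smallest adjusted p of 0.170. At an unadjusted p under 0.05 there were 590 genes with higher and 493 with lower levels in pCI, 1083 in all, where 919.7 would be expected by chance among 18394. Of 100 divisions of the libraries into equal groups, the real one included, 19 gave at least as many. The limma-voom test called 0 genes, with 1186 at an unadjusted p under 0.05. DESeq2 called 14 genes higher and 27 lower in pCI and had 1200 at an unadjusted p under 0.05. The 41 DESeq2 genes had the same direction in edgeR, where their adjusted p ran from 0.170 to 0.592. Of the DESeq2 genes, 6 of the 14 higher and 16 of the 27 lower differed by at least 2-fold, and 9 had a mean under 1 CPM. The 4 genes named above are among them, with DESeq2 adjusted p of 5.08e-06 for MGP_C57BL6NJ_G0011451, 0.000372 for MGP_C57BL6NJ_G0013263, 6.84e-05 for MGP_C57BL6NJ_G0033734 and 0.00217 for MGP_C57BL6NJ_G0033950. In data simulated from these libraries with 200 changed genes, 36 of 176 DESeq2 calls were false against 5 of 132 edgeR calls. For DESeq2 that share was larger than its threshold of 0.05. The simulation was a single draw from edgeR's own per-gene dispersions, a setting that may favour edgeR. It does not settle how many of the 41 are false. Without pCI replicate 2, DESeq2 called 25 genes higher and 111 lower, and without pCI replicate 6 it called 67 higher and 58 lower.

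The groups did not overlap at all for 85 genes, of which 39 were higher and 46 lower in pCI, where 39.8 would be expected by chance for 6 against 6 libraries. Of the 41 DESeq2 genes, 25 were among them. Of all 462 divisions of the 12 libraries into 6 and 6, the real one included, 43 gave at least 85 such genes. The limma-voom 95% interval of the fold change lay within 2-fold for 14131 of the 15178 genes with a mean of at least 1 CPM (93.1%), and within 1.5-fold for 11315 of them (74.5%). In the simulation, edgeR recovered 31.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 90.9% of those changed 4-fold. That simulation held 200 changed genes and drew each gene independently, without co-varying groups. Recovery in the real libraries, or with fewer changed genes, may be lower.

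Over the whole profile, the division into tCI and pCI held 10.9% of the variance in log2 CPM of the tested genes, where a random division holds 9.09% on average (exact two-group permutation over 924 assignments, p = 0.145). The first principal component held 21.3% of the variance and the second 16.2%. Neither differed detectably between the groups (exact two-sided permutation p = 0.426 and 0.184). The library farthest out was pCI replicate 2, and tCI replicate 6 was the next.

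**Figure D2:**
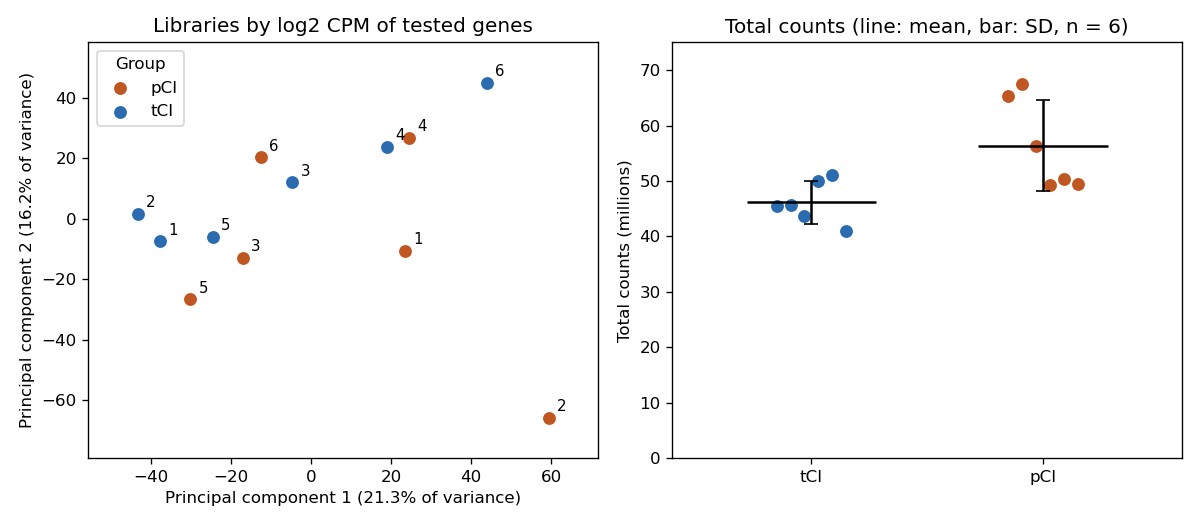
Left, the first and second principal components of log2 CPM, with 21.3% and 16.2% of the variance, 1 point per library labelled with its replicate number. Right, total counts per library in M, with the mean (line) and SD (bar) of 46.1 ± 3.83 in tCI and 56.3 ± 8.23 in pCI (n = 6 each); pCI replicate 2 stands apart at the lower right of the components.

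Genes that varied together were grouped without reference to tCI and pCI, which gave 11 groups with 591 of 1013 variable genes. This grouping was chosen after seeing the data. Group 10, of 11 genes, was lower in pCI. Its mean log2 CPM was 1.78 ± 0.79 in tCI and -0.55 ± 0.53 in pCI (SD, n = 6), a difference of -2.33 (exact two-sided permutation p = 0.00216, the smallest that 6 against 6 libraries allow, and 0.0238 after Benjamini-Hochberg adjustment over the 11 groups). For this mean, every pCI library lay below every tCI library, the closest being pCI replicate 6 at 0.40 and tCI replicate 1 at 0.54. Taken singly, 3 of the 11 genes of group 10 separated the libraries in this way. The log2 fold changes of its 11 genes ran from -6.10 to -0.76 with a median of -1.70. All 11 had an unadjusted p under 0.05 in edgeR but none an adjusted p under 0.170, and 8 of them were called by DESeq2. The genes were grouped by correlation over the same libraries, so these counts largely repeat the difference in the mean. They are no separate evidence. Within tCI, the level of group 10 was 0.54 in replicate 1 and 1.02 in replicate 5, against 2.18 to 2.35 in the other 4 libraries. With a stricter choice of variable genes (SD over 0.8) or a tighter clustering (height 0.2), 0 groups passed the test.

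The other 10 groups did not differ detectably between pCI and tCI, with adjusted exact permutation p from 0.757 to 0.859. The largest of them, group 1 with 208 genes, was low in a single library. Its mean log2 CPM was 2.77 ± 0.10 in tCI (SD, n = 6) and 0.14 in pCI replicate 2, and the 5 other pCI libraries had a mean of 2.71 ± 0.27 (SD). All 208 genes had their lowest level in pCI replicate 2. Clustering by correlation over the same libraries favours such a pattern, so that count is no separate evidence. They took 0.0626% of the counts of that library and 0.269% to 0.416% in each of the others. Group 6, of 27 genes, had a mean log2 CPM of 4.21 in tCI replicate 4, 1.81 in tCI replicate 1 and 1.72 in pCI replicate 6, against 0.73 or less in the other libraries.

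**Figure D3:**
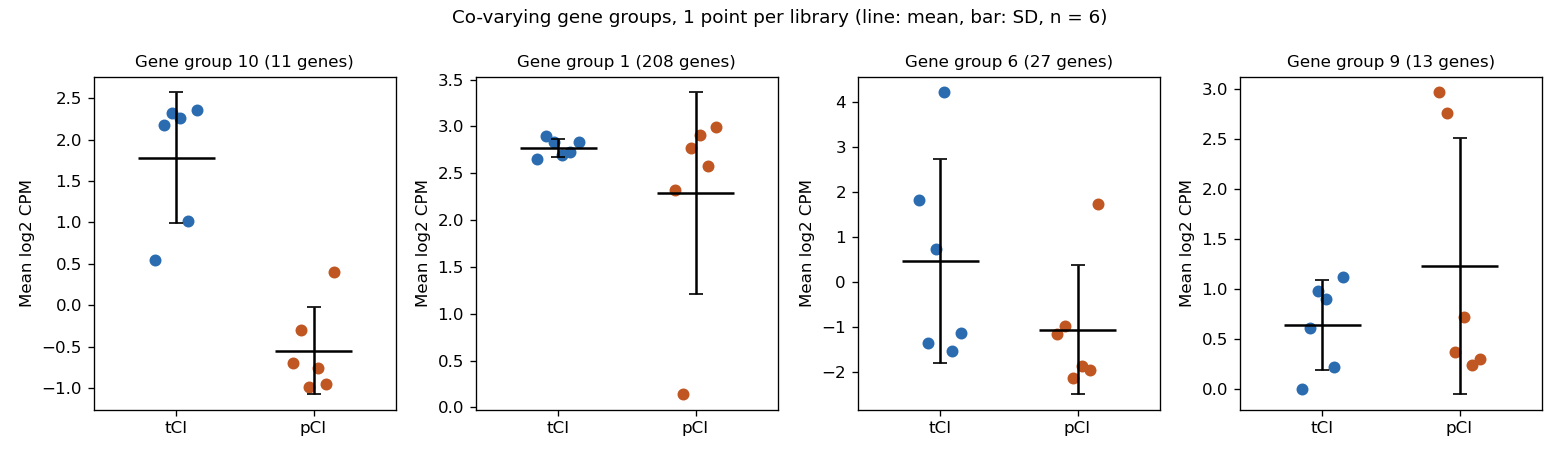
Mean log2 CPM of 4 of the 11 groups of co-varying genes, 1 point per library, with the mean (line) and SD (bar) of the 6 libraries of tCI and pCI. Group 10 is lower in all pCI libraries (-0.55 ± 0.53 against 1.78 ± 0.79), and group 1 is low in pCI replicate 2 alone, at 0.14.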

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

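The test of a missing cell type or part of the tissue, and the gene groups themselves, were chosen only after the results were seen. Values per library (library composition, principal components, the named genes and the gene groups) were searched within each group for a library lying farther from its nearest neighbour than Dixon's 95% critical value allows. Over 40 sets of 6 libraries, 4 such values were found, where chance gives about 1 in 20, or 2. The named genes and gene groups were chosen from these same libraries, and clustering by correlation favours single-library patterns. That rate is therefore only a rough guide.

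MGP_C57BL6NJ_G0011451 was lowest in pCI replicate 3, at a log2 CPM of -1.26 against -0.40 to 0.093 in the other pCI libraries. Group 6 (27 genes) was high in pCI replicate 6, at a mean log2 CPM of 1.72 against -2.15 to -0.98 in the other pCI libraries. Group 11 (11 genes) was low in tCI replicate 2, at -1.83 against 0.95 to 1.92 in the other tCI libraries.

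Group 1 (208 genes) was low in pCI replicate 2, at a mean log2 CPM of 0.14 against 2.32 to 3.00 in the other pCI libraries. The drop against the other 11 libraries was -2.61 and became -2.56 when every library was thinned to the smallest total. Thinning leaves the expected CPM of a gene nearly unchanged, so that result decides little about depth. This library had the highest total of the 12, which argues against a low total as the cause. The other tested genes had a median deviation of 0.056 in that library, so most genes did not share the drop. TMM scaling itself brings most genes near a common level, so this median cannot decide on the scaling factor. The TMM factor was 1.054 in that library, against 0.954 to 1.050 in the others. A cell type or part of the tissue missing from that piece may account for the drop, but 0 of the 208 identifiers could be matched to a symbol, so this could not be tested against marker genes. The design gives this library no condition of its own, so no biological explanation was tested.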

How the results depend on the processing

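The robust fit, thinning, division of counts by 4, leaving out 2 libraries together, DESeq2 without each library or with the block, and every setting of the gene groups were chosen after seeing the data. The edgeR count of 0 genes higher in pCI held under all edgeR and limma-voom settings at an adjusted p, and the count lower ran from 0 to 1 with 1 library left out. That 1 gene was MGP_C57BL6NJ_G0011451 without tCI replicate 5 (adjusted p 0.0139, over its alternatives 5.08e-06 to 0.585) and another gene of group 10 without pCI replicate 6 (0.0214). The latter then had a log2 fold change of -8.73, beyond the -6.10 that was the lowest of group 10 with all libraries. DESeq2 called 14 higher and 27 lower, and an unadjusted p under 0.05 with at least 2-fold gave 50 and 97. The 1083 genes at an unadjusted p under 0.05 became 2255 with no filter, where more genes are tested, 1186 with limma-voom, and 1683 with limma-voom and sample quality weights. The named genes kept their direction in every alternative run, with log2 fold changes of -2.67 to -2.09 for MGP_C57BL6NJ_G0011451, -5.73 to -4.53 for MGP_C57BL6NJ_G0013263, 3.18 to 4.29 for MGP_C57BL6NJ_G0033734 and 0.35 to 0.42 for MGP_C57BL6NJ_G0033950. Over 1.5-fold moves came for MGP_C57BL6NJ_G0013263 without pCI replicate 6 (-5.73), and for MGP_C57BL6NJ_G0033734 with limma-voom (3.44), with its sample quality weights (3.18), with the replicate block (3.35) and with the title number (3.45).

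With 1 library left out, DESeq2 called 7 to 67 genes higher and 20 to 111 lower. The extremes were 7 without pCI replicate 1, 67 without pCI replicate 6, 20 without tCI replicate 4 or 5 and 111 without pCI replicate 2. It called 45 lower without tCI replicate 1, 9 higher without tCI replicate 5 and 25 higher without pCI replicate 4. With counts divided by 4 it called 6 and 17, and without tCI replicate 6 and pCI replicate 2 it called 30 and 93, of which 36 were among the 41. The cause was not tested. Under SD minimum 0.8 and under height 0.2, 0 gene groups differed, for a cause not tested.

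The replicate numbers were not taken to pair the libraries: deviations of same-numbered libraries correlated at -0.158 to 0.167, and 0 of 6 tCI libraries correlated best with their own number. With the replicate block edgeR called 0 genes (856 at an unadjusted p under 0.05), DESeq2 called 17 higher and 41 lower, the difference in total counts of 10.2 M had an exact p of 0.125, and group 10 an exact p of 0.0313. Thinning every library to the smallest total left 38 DESeq2 calls, 36 of them among the 41, and what depth limits beyond this was not tested.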

Other observations

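The tests against other divisions of the libraries for edgeR calls, and of an added source for group 10, were chosen only after the results were seen, as were the gene groups. Several groups of co-varying genes spread widely within both tCI and pCI. Group 2 (95 genes) ran from a mean log2 CPM of 0.92 in tCI replicate 1 to 3.98 in tCI replicate 4, and from 1.84 to 3.48 in pCI. Group 3 (72 genes) was at 0.34 in tCI replicate 6 and at 1.73 to 3.11 in the other libraries. Group 4 (61 genes) was highest in tCI replicate 6 at 3.85 and pCI replicate 4 at 3.76, and lowest in tCI replicate 5 at 0.66. Group 9 (13 genes) was at 2.97 in pCI replicate 1 and 2.77 in pCI replicate 2, against 1.12 or less in the other libraries. Those 2 libraries also had the highest levels of MGP_C57BL6NJ_G0033734, 23.4 and 18.3 CPM, and the highest totals, 65.3 and 67.5 M.

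Group 10 (11 genes) was lower in pCI by -2.33 in mean log2 CPM. The difference was -2.27 (exact permutation p = 0.00216) when every library was thinned to the smallest total. Thinning leaves the expected CPM of a gene nearly unchanged, so that result decides little about the difference in total counts. RNA or cells of 1 other source in some tCI pieces may also give such a set. Its genes correlated at 0.831 on average, but they were grouped by correlation, so that value decides nothing, and no marker could be looked up. That source and an effect of the labelled condition could not be told apart here for these 11 genes, since no identifier matched a symbol in the reference tables used. A difference between pCI and tCI animals stays open as a hypothesis.

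The 41 genes called by DESeq2 became 38 after thinning, 36 of them shared. Since thinning leaves the expected CPM of a gene nearly unchanged, this also decides little about unequal counting depth. Other differences tied to total counts were not tested by thinning. With counts divided by 4 there were 23, of which 22 were shared, so the part that the count scale plays stays open. Chance could not be excluded for them: 5 of 50 divisions of the 12 libraries into 6 and 6, the real one included, gave at least 41 genes, and the highest other gave 1289. A count so far above the real one, from tCI replicates 1, 2, 3 and 5 with pCI replicates 3 and 5 against the rest, points to a structure of the samples that does not follow tCI and pCI, though that division was picked as the highest of those drawn and the labels give no batch.

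Chance could not be excluded for 2 other counts over all genes either. For the 1083 genes at an unadjusted p under 0.05 in edgeR, 19 of 100 divisions gave as many, and the highest other gave 3297. For the 85 genes whose groups do not overlap, 43 of all 462 divisions gave as many, and the highest other gave 767, from tCI replicates 1, 2 and 5 with pCI replicates 3, 5 and 6 against the rest. For edgeR calls the real count is 0, so all 100 of 100 divisions give at least as many and the comparison says nothing about chance; the highest other gave 352.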
